A study of Danio rerio with 8 samples.

How the data were processed

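RNA was extracted from whole zebrafish larvae at 2 days of age, and a sequencing library was made from total RNA for each of 8 samples, 4 controls and 4 nphp8 mutants, per the labels' protocols. The library preparation was a commercial provider's own protocol, and whether it selected polyadenylated RNA or kept the strand is not given in the sources used here. Reads were aligned with STAR 2.7.3a and quantified with RSEM 1.3.1 against the GRCz11 genome build, per the submitters' processing notes. The authors deposited a single table of TPM, the relative abundance of transcripts, with a row per Ensembl gene and a column per library, printed to 2 decimals. TPM divides the reads assigned to a gene by its length and then scales every library to the same sum, so the values are shares within a library. The number of reads behind a value cannot be recovered from TPM, so the depth of each library is unknown and no interval or detection limit that needs a count is given. Reads that fit several near-identical genes are divided among them by RSEM with an estimate, which makes single members of the crystallin, hemoglobin, her4 and her15, and troponin families uncertain. Overlapping and antisense genes are uncertain as well, because the strand setting is not known.

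Groups and replicate numbers were taken from the sample titles. The labels give the controls a wild-type genotype, whereas the series design calls them siblings, and nothing states how many larvae or clutches went into each sample. The p-values therefore measure only the spread between these samples, which may be technical. No batch, date or time of collection is given.

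Gene symbols came from a table that pairs Ensembl gene identifiers with symbols, in which 29201 of the 32520 identifiers (89.8%) had a symbol. Many of these symbols are human-style and shared by the duplicated zebrafish copies, and 6314 identifiers shared a symbol with another. The copies are told apart by their Ensembl identifier. The order of genes along chromosomes came from a RefSeq gene table of another assembly, GRCz12tu, which was used for names and neighbours alone, and no coordinates are given. By unique symbol, 16968 identifiers were placed, 527 of them on the chromosome of rpgrip1l. The planned windows of distance around rpgrip1l were replaced by windows of the nearest 25, 50 and 100 placed genes on each side, because the builds differ. No genome sequence was used here, so GC content and gene length were not examined.

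The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided) on log2(TPM + 1) with no covariate, over 16560 genes with a mean of at least 1 TPM across the 8 libraries. P-values were adjusted by the Benjamini-Hochberg method, a gene was called changed at an adjusted p under 0.05, and a stricter count also required an absolute log2 change of at least 1. Every adjusted p of a single gene below comes from this limma fit unless another is named. A log2 change is the mutant mean minus the control mean on the log2(TPM + 1) scale, which understates the change of genes of a few TPM. Folds are ratios of mean TPM. The rpgrip1l level was also compared by an exact permutation test over the 70 assignments of 8 libraries, whose smallest two-sided p is 0.0286. Annotation used Python 3.11.15 with pandas 2.3.3, and plots used matplotlib 3.10.9.

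Before the data were examined, 39 gene lists with 1462 members in all were fixed from general knowledge of zebrafish gene names, and 1360 members were matched to an identifier by symbol, RefSeq synonym or the symbol without its copy letter. They cover the core circadian clock, the PAR bZIP and E4BP4 clock output factors, light-induced genes and DNA repair, pineal and phototransduction, cilia (transition zone and nephronophthisis, intraflagellar transport and BBSome, motile cilia), signalling (Hedgehog, canonical Wnt, planar cell polarity and non-canonical Wnt, Notch), stress and metabolism (p53, unfolded protein response, heat shock, NRF2, nonsense-mediated decay, glucocorticoid and metabolic hormone targets, sterol synthesis, glycolysis and hypoxia, mitochondrially encoded transcripts, cytosolic ribosomal proteins, S-phase and mitosis, replication-dependent histones, innate immunity) and tissues (pronephros, myeloid cells, erythroid cells, skeletal muscle, heart, lens, neurons and progenitors, pigment cells, hatching gland, liver and yolk syncytial layer, exocrine pancreas and gut, skin and ionocytes, notochord and extracellular matrix, vasculature, left-right patterning). Each list with at least 5 tested members was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and limma's fry, which compares no list with other genes, were alternatives. With an estimated correlation camera also uses the residual degrees of freedom of the fit, far fewer than with the preset one. A call can therefore be lost without a larger correlation. Genes near rpgrip1l were compared with all other placed genes by Fisher's exact test, two-sided.

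The genes named were chosen by a rule fixed together with the lists. It takes rpgrip1l in every library and its paralogue rpgrip1, the 10 largest increases and the 10 largest decreases among changed genes whose 4 mutant libraries all lay beyond all 4 controls and whose symbol was not a placeholder, the largest placeholder-named gene in each direction, every core clock gene that passed and up to 6 that did not, and up to 4 members with the smallest p of every other list. A few genes the rule takes are not reported here, though they stay in all counts except that of single libraries standing apart. Genes outside the rule are said to have been chosen after their values were seen. The alternatives were 3 other pseudocounts, 3 other filters, 3 rescalings, 3 other variance or weight settings, a permutation test per gene, a fit with the replicate number as a term, and leaving out each library in turn.

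The procedure was tested on simulated data with each gene's mean over all 8 libraries and its spread within groups, for the 16560 genes. In these data 50 genes were changed at each of 4 sizes. It called 30% of the genes changed by 0.25 on the log2 scale in the comparison of controls with mutants, 92% of those changed by 0.5, and 98% of those changed by 1 or 2. Unchanged genes made up 4.22% of the calls. With nothing changed it called 0 genes at an adjusted p and 0 lists, and with a single list moved it called that list alone. Each simulated gene was drawn independently, whereas estimated correlations within the real lists reached 0.548 (mitochondrially encoded transcripts). The simulation therefore cannot show how often lists of correlated genes pass camera by chance.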

Results

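Gene expression was measured by RNA sequencing in whole zebrafish larvae at 2 days of age, in 4 libraries from larvae lacking both the maternal and the zygotic function of nphp8 (allele sa24730) and in 4 libraries from controls. The gene nphp8 is listed under its other name, rpgrip1l, and encodes a protein of the transition zone at the base of the cilium that is mutated in human nephronophthisis and Joubert syndrome. The comparison asked which transcripts differ in these mutants, and the title of the series singles out circadian clock genes. The level of the protein was not measured in these data. Values are TPM, which are scaled to the same sum in every library and carry no information on depth, so the depth is unknown. Between 23637 and 23964 genes had a value above 0 in a library. The 10 most abundant genes of a library took 8.32% to 8.57% of the TPM in controls and 8.94% to 9.12% in mutants. Mitochondrially encoded transcripts took 1.80% to 1.93% in controls and 2.06% to 2.24% in mutants.

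The transcript of the mutated gene itself was lower in every mutant library. RPGRIP1L (ENSDARG00000051754) stood at 2.75, 2.6, 2.26 and 2.17 TPM in control replicates 1 to 4 and at 0.75, 0.72, 0.77 and 0.78 TPM in mutant replicates 1 to 4. The means were 2.45 ± 0.275 TPM and 0.755 ± 0.0265 TPM (SD, n = 4 each), a ratio of 0.309, and the difference reached the smallest p of the exact permutation test (p = 0.0286, two-sided). On the log2 scale it fell by 0.97 (SE 0.0798, limma adjusted p = 2.47e-05). Its paralogue rpgrip1 (ENSDARG00000076055) lay below the expression filter, at 0.31 ± 0.125 TPM in controls and 0.05 ± 0.00816 TPM in mutants. When genes of any level were tested it was lower as well, by a log2 change of -0.31 (limma adjusted p = 0.0122), at levels where a change in TPM rests on few reads.

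Many genes differed, most of them by small amounts. Of 16560 genes tested, 3745 changed in the mutants (22.6%, limma adjusted p under 0.05), 1543 upwards and 2202 downwards. Among changed genes the median absolute log2 change was 0.262 and the upper quartile 0.372, and 68 genes changed by at least 1 on the log2 scale, 32 of them upwards and 36 downwards. The 4 mutant libraries lay wholly beyond the 4 controls for 4324 genes tested (26.1%), against 2.86% by chance. The first principal component held 37.4% of the variance and separated the groups completely, and Spearman correlations of whole profiles ran from 0.986 to 0.989 within groups and from 0.977 to 0.982 between them. The share of higher calls moved from 41.2% to 50.8% when libraries were rescaled without mitochondrial genes and the 50 most abundant genes. The stricter count depended on the pseudocount, with 147 genes at 0.1 and 17 at 5, and was 36 among genes of at least 5 TPM.

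The largest increases were in light-responsive and clock genes and in lens crystallins. A cryptochrome gene, CRY1 (ENSDARG00000045768), rose 4.77-fold, from 3.05 ± 0.219 to 14.5 ± 1.33 TPM (SD, n = 4 each), and the period gene PER2 rose 5.52-fold, from 1.21 ± 0.182 to 6.67 ± 0.217 TPM. The 6-4 photolyase gene cry5 rose 5.38-fold, lonrf1 3.38-fold and the cryptochrome gene cry3b 2.87-fold. The γM-crystallin genes crygm2d16, crygm2d2 and crygm2d5 rose 4.41-fold, 2.59-fold and 2.53-fold, with reads shared among near-identical copies. The cathepsin L-like gene ctsll rose 3.59-fold and ANKRD1 (ENSDARG00000076192), a muscle ankyrin-repeat gene, 2.88-fold. Among genes with placeholder names, si:ch211-114l13.11 had the largest increase, from 0.37 ± 0.0935 to 4.22 ± 0.713 TPM. The limma adjusted p of these genes ran from 4.14e-09 for crygm2d5 to 8.96e-06 for ANKRD1.

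The largest decreases held heat shock and collagen chaperones and immediate-early transcription factors. SERPINH1 (ENSDARG00000019949), the collagen chaperone also called Hsp47, fell from 333.1 ± 7.43 to 93.9 ± 0.805 TPM, and the cytosolic chaperone HSP90AA1 fell from 57.0 ± 1.46 to 18.1 ± 0.704 TPM (SD, n = 4 each). FOS fell from 25.8 ± 0.888 to 6.49 ± 0.0971 TPM, egr1 from 8.20 ± 0.584 to 2.58 ± 0.323 TPM, JUNB (ENSDARG00000074378) from 15.8 ± 1.63 to 5.65 ± 0.623 TPM, and the AP-1 partner JDP2 (ENSDARG00000020133) from 13.6 ± 1.0 to 5.15 ± 0.58 TPM. The chemokine gene ccl39.3 fell from 8.36 ± 2.02 to 3.17 ± 1.47 TPM, dbndd1 from 2.46 ± 0.304 to 0.358 ± 0.0287 TPM and the channel gene trpm1b from 16.0 ± 1.34 to 6.63 ± 0.644 TPM. The placeholder-named gene zgc:173585 had the largest log2 change of all named genes, from 73.9 ± 2.47 to 1.88 ± 0.76 TPM. Limma adjusted p-values ran from 5.39e-11 for SERPINH1 to 0.00599 for ccl39.3. No label gives the batch or time of collection. For the chaperone and immediate-early genes, unequal handling of the groups therefore cannot be told apart from genotype.

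**Figure D1:**
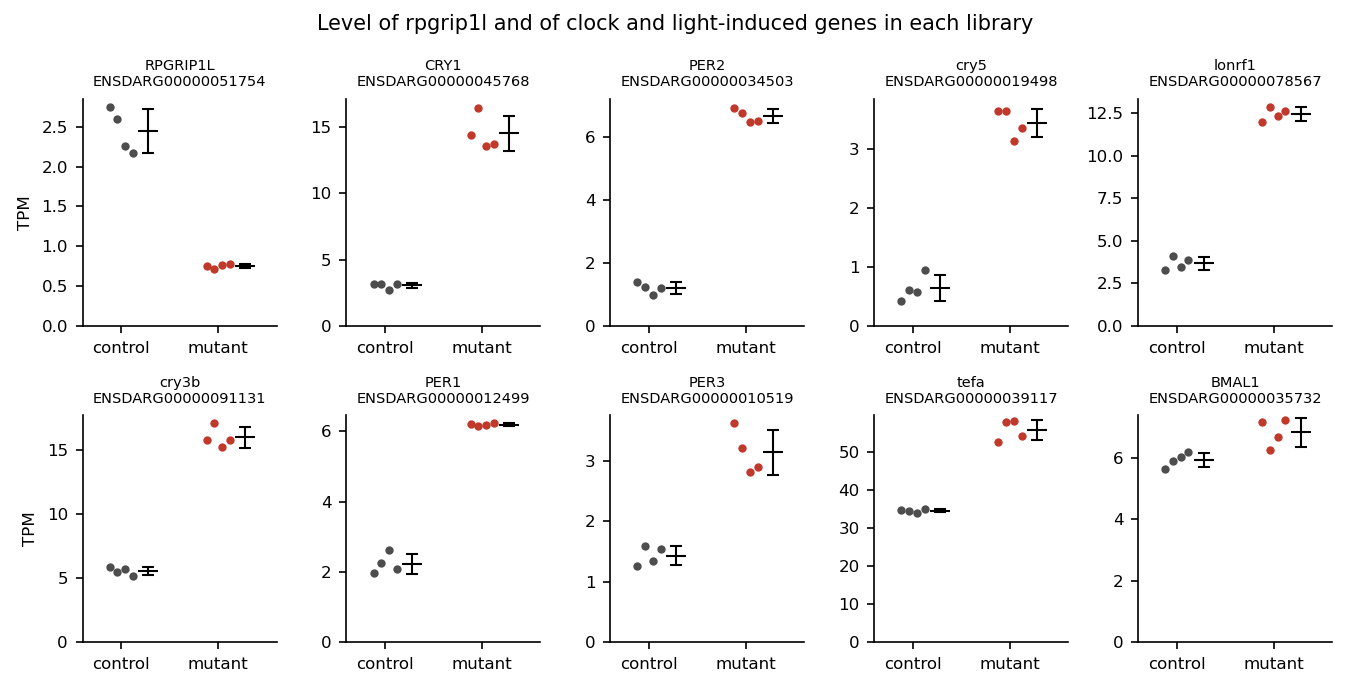
Level in TPM (vertical axes, from 0) of RPGRIP1L, 8 clock or light-induced genes and BMAL1 in the 4 control libraries (grey points) and the 4 mutant libraries (red points), with the mean and SD of each group in black. CRY1 stood at 3.05 TPM in controls and 14.5 TPM in mutants and PER2 at 1.21 and 6.67 TPM, whereas BMAL1 stood at 5.94 and 6.84 TPM and did not pass the test.

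Clock genes rose in part of the core feedback loop. Of 28 core circadian clock genes tested, 8 rose, 1 fell and 19 did not pass, and adjusted over the list alone 10 were higher and 2 lower. Beside CRY1, PER2 and cry3b, the period genes PER1 (ENSDARG00000012499) and PER3 rose 2.77-fold and 2.19-fold, and NR1D2, CRY2 and the clock kinase CSNK1D rose 1.4-fold, 1.31-fold and 1.15-fold. BHLHE40, a repressor of clock transcription, fell from 41.9 ± 0.609 to 37.9 ± 0.166 TPM (SD, n = 4 each). The limma adjusted p-values of these 9 genes reached 0.0061 at most. The 6 members closest to the threshold among those that did not pass were BMAL1 (ENSDARG00000035732; ratio 1.15, adjusted p = 0.0563), rorcb (ratio 0.698), nr1d2a (1.5), RORB (1.25), BHLHE41 (0.858) and cry4 (0.933). Leaving out mutant replicate 2 brought BMAL1 and rorcb past the threshold (limma adjusted p = 0.0293 for BMAL1), as leaving out control replicate 4 did for rorcb and control replicate 2 for nr1d2a. The list as a whole was higher by camera (adjusted p = 0.000703), but not with an estimated correlation (adjusted p = 0.0621). The estimated correlation of the clock list was 0.0122, close to the preset 0.01. The loss of its call thus follows mainly from the fewer degrees of freedom of that test. The series title names this group, and whether the study chose it from these samples is not given in the sources used here, so its direction is not taken as independent evidence.

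Light-induced and DNA repair genes rose as a group, and this call also held with an estimated correlation. In zebrafish many tissues sense light directly, and these genes respond to it. Of 18 tested, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 change of 0.20 and a mean of 0.58, a camera adjusted p = 2.36e-09 and an adjusted p = 0.0337 with an estimated correlation. The output factor gene tefa rose 1.61-fold, from 34.6 ± 0.419 to 55.7 ± 2.67 TPM (SD, n = 4 each). DDB2, for recognition of ultraviolet damage, and cry-dash rose 2.09-fold and 2.17-fold, and these 2 were chosen after their values were seen. The list shares CRY1 and PER2 with the clock list and tefa with the output list. Without shared members 8 of 14 rose and 0 fell (camera adjusted p = 1.66e-05), and the clock list without them kept a camera adjusted p = 0.0214 with 6 of 25 higher and 1 lower. Both reduced lists were tested at the preset correlation alone. Of 5 PAR bZIP and E4BP4 output factors, tefa and nfil3-5 (1.15-fold) rose and 0 fell, while hlfa (ratio 1.22) and tefb (ratio 1.1) did not pass. That list was higher by camera (adjusted p = 0.00815), but not with an estimated correlation (adjusted p = 0.164); over the list alone 3 were higher.

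Lens genes rose almost without exception. Of 43 tested, 39 rose, 0 fell and 4 did not pass (40 higher over the list alone), with a median log2 change of 0.60, a camera adjusted p = 1.03e-41 and an adjusted p = 0.00156 with an estimated correlation. The β-crystallin gene crybb1l1 rose from 165.6 ± 1.72 to 282.9 ± 5.17 TPM, and crygm2d20 and crygm2d21 rose 2.23-fold and 1.89-fold. Many of the list's members are near-identical γM-crystallin copies, so their number overstates the independent evidence.

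Red blood cell and muscle genes rose too. Of 25 erythroid genes, 16 rose and 2 fell, with a median log2 change of 0.37, a camera adjusted p = 2.46e-12 and an adjusted p = 0.00347 with an estimated correlation (16 higher and 3 lower over the list alone). The embryonic globins hbae3 and hbae1.3 rose 1.80-fold, nt5c2l1 1.76-fold and the anion exchanger SLC4A1 (ENSDARG00000012881) 2.01-fold, from 60.2 ± 1.07 to 121 ± 2.43 TPM (SD, n = 4 each). The 2 members that fell, named after their values were seen, were blf (ratio 0.689) and the other SLC4A1 copy (ENSDARG00000024560, ratio 0.671). Of 66 skeletal muscle genes, 37 rose and 3 fell (39 and 4 over the list alone), with a median log2 change of 0.17, a camera adjusted p = 5.47e-15 and an adjusted p = 0.0337 with an estimated correlation. Myosin heavy chain myhz2 rose 1.79-fold, mybpc2b 1.56-fold, TNNI2 (ENSDARG00000029069) 1.39-fold and muscle creatine kinase ckma 1.25-fold. The 3 that fell, again named after their values were seen, were the differentiation factor MYOG (ratio 0.699), tcap (ratio 0.732) and a TNNI2 copy (ENSDARG00000035958, ratio 0.881).

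Chaperones of the endoplasmic reticulum fell together. Of 30 unfolded protein response genes, 24 fell and 2 rose, over all genes and over the list alone, with a median log2 change of -0.25, a camera adjusted p = 1.62e-09 and an adjusted p = 0.0337 with an estimated correlation. HSPA5, the central chaperone of this compartment, fell from 192.6 ± 3.02 to 133.1 ± 3.66 TPM and HSP90B1 from 138.2 ± 2.94 to 94.2 ± 2.42 TPM (SD, n = 4 each). PDIA6 and the stress-induced factor ATF3 had ratios of 0.801 and 0.539. The 2 members that rose, CHAC1 (1.23-fold) and atf4b (1.15-fold), were named after their values were seen. These 5 lists, light-induced genes, lens, erythroid cells, skeletal muscle and the unfolded protein response, were the ones that passed camera with both correlations, of 18 that passed with the preset one.

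**Figure D2:**
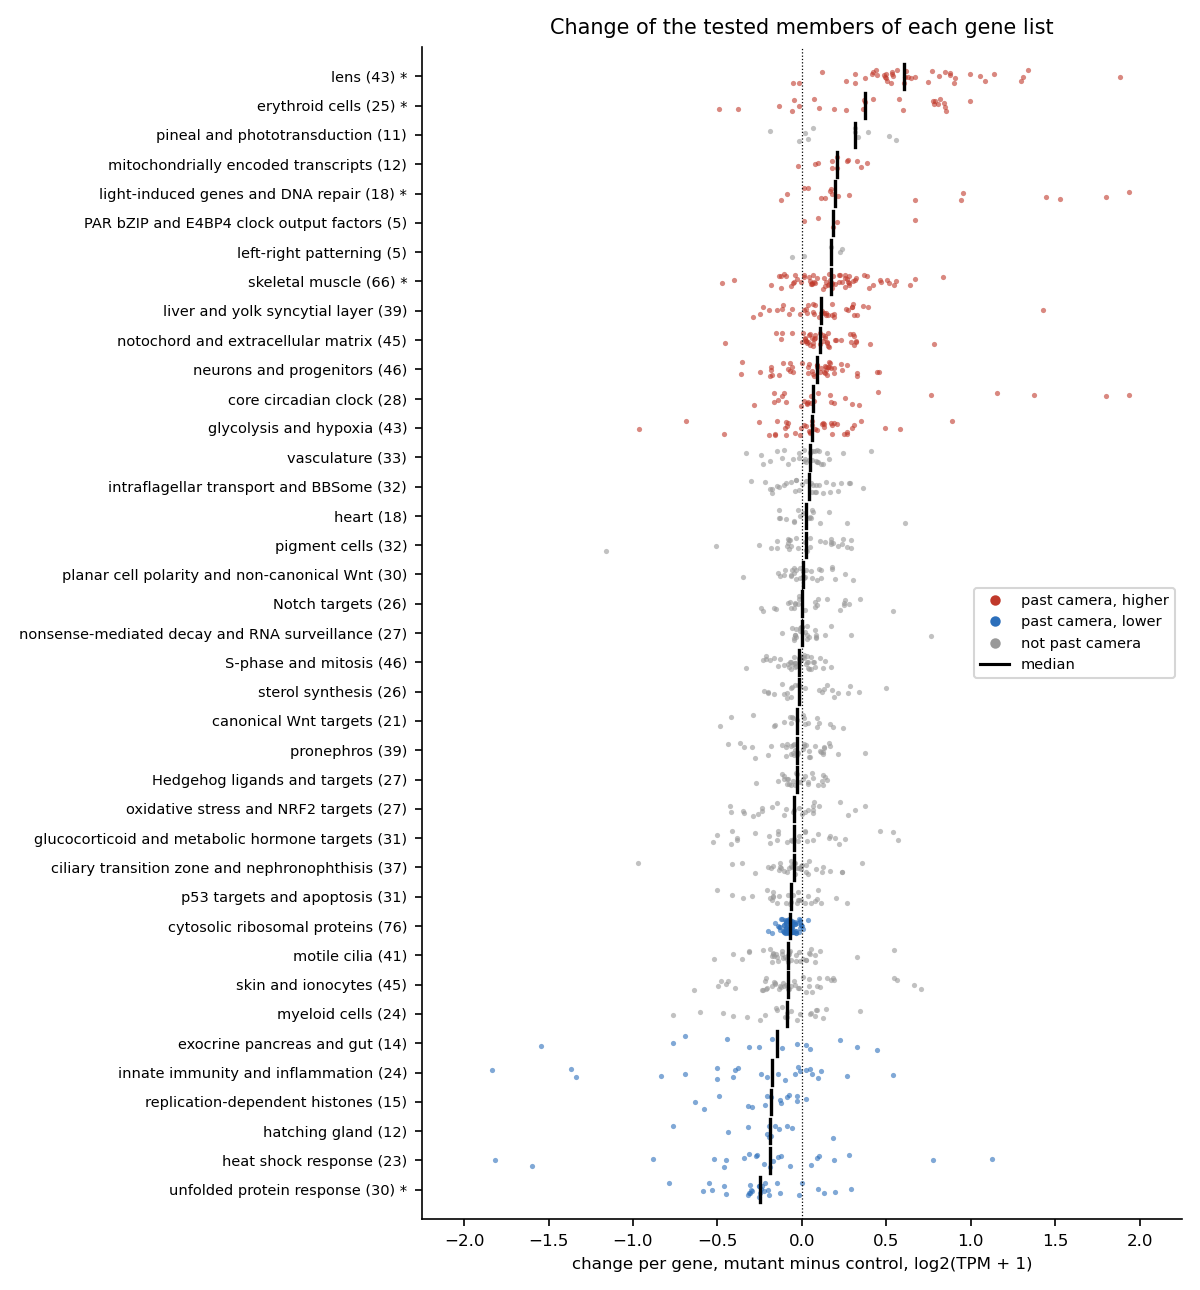
Change of each tested gene on the log2(TPM + 1) scale, mutant minus control (horizontal axis), for the 39 gene lists (with the number of genes tested in brackets); each point is a gene, black bars are medians, red and blue mark lists past camera at the preset correlation, and an asterisk marks those also past it with an estimated correlation. Lens lies highest with a median of 0.60 and the unfolded protein response lowest with a median of -0.25.

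Heat shock genes fell for the most part. Of 23 heat shock genes, 14 fell and 4 rose (15 and 4 over the list alone). The camera call (adjusted p = 7.05e-05) was lost with an estimated correlation (adjusted p = 0.124). Beside SERPINH1 and HSP90AA1, hsp90aa1.1 fell from 246.2 ± 3.4 to 133 ± 3.08 TPM and the mitochondrial co-chaperone HSPE1 fell by 0.27 on the log2 scale. The 4 that rose, named after their values were seen, were hsp70.1 (from 0.802 ± 0.168 to 2.94 ± 0.558 TPM), hsp70l (from 0.602 ± 0.107 to 1.74 ± 0.236 TPM), HSF2 (1.23-fold) and hspb9 (1.14-fold), whereas hsp70.3, named likewise, fell (ratio 0.904). Of 24 innate immunity and inflammation genes, 10 fell and 1 rose (12 and 1 over the list alone), with a camera adjusted p = 0.00126 and an adjusted p = 0.0512 with an estimated correlation. Its strongest members were the immediate-early factors FOS, egr1 and both JUNB copies (ENSDARG00000104773 at a ratio of 0.55), which many stimuli induce outside immunity as well. Unequal handling of the groups at collection was not tested for this list or the heat shock list. The member that rose, named after its value was seen, was the collagenase gene mmp13a (2.0-fold). Without gene IDs that share a symbol the list did not pass (camera adjusted p = 0.075). For the full list the estimated correlation was -4.38e-05, below the preset 0.01. Its higher p with the estimate thus follows from the fewer degrees of freedom of that test.

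Several tissue lists passed only with the preset correlation. Of 45 notochord and matrix genes 22 rose and 1 fell (the same counts over the list alone; camera adjusted p = 1.3e-07), among them MATN3 (ENSDARG00000069245, 1.82-fold), TGFBI (1.15-fold) and col1a1a (1.11-fold), whereas CCN2 fell to a ratio of 0.725. With an estimated correlation its adjusted p = 0.164. Of 39 liver and yolk syncytial layer genes 20 rose and 7 fell (22 and 7 over the list alone; camera adjusted p = 6.01e-06, adjusted p = 0.12 with an estimated correlation), with a2ml, cfhl4 and fga higher by 1.32-fold, 1.23-fold and 1.29-fold. Of 12 hatching gland genes 8 fell and 0 rose (9 lower and 1 higher over the list alone; camera adjusted p = 6.25e-05, adjusted p = 0.0782 with an estimated correlation). The hatching enzyme gene he1.1 fell from 4070 ± 57.6 to 3590 ± 79.9 TPM (SD, n = 4 each), and he1.2, he1.3 and ctslb had ratios of 0.872, 0.51 and 0.802. Of 14 exocrine pancreas and gut genes 5 fell and 0 rose (6 lower and 2 higher over the list alone; camera adjusted p = 0.038, adjusted p = 0.199 with an estimated correlation). FABP2 fell from 351.3 ± 11.5 to 258 ± 9.13 TPM, the elastase gene CELA1 (ENSDARG00000017314) had a ratio of 0.549 and FABP1 (ENSDARG00000059227) one of 0.92, and the pancreas factor gene PTF1A (ratio 0.544) was named after its value was seen. This call was also lost among genes of at least 5 TPM (adjusted p = 0.155), without gene IDs that share a symbol (0.35), without members whose symbol also names another gene (0.0591), without control replicate 2 (0.0627) and without mutant replicate 2 (0.0641). Of 46 neuronal and progenitor genes 13 rose and 7 fell (15 and 8 over the list alone; camera adjusted p = 0.0296, adjusted p = 0.164 with an estimated correlation), with the progenitor genes SOX2 and SOX3 lower (ratios 0.877 and 0.88) and SNCG (ENSDARG00000034423) and FABP7 (ENSDARG00000007697) 1.25-fold and 1.14-fold higher. That call was lost among genes of at least 5 TPM (adjusted p = 0.0653), without mutant replicate 3 (0.0758), without gene IDs that share a symbol (0.63) and without members whose symbol also names another gene (0.056).

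All 9 changed genes of 12 tested mitochondrially encoded transcripts rose (9 over the list alone; camera adjusted p = 8.33e-08, adjusted p = 0.164 with an estimated correlation), with MT-CO1 1.31-fold, mt-nd4l 1.26-fold, MT-ND4 1.21-fold and MT-ATP6 1.21-fold higher. Of 76 cytosolic ribosomal protein genes 36 fell and 0 rose (40 over the list alone; camera adjusted p = 1.36e-09, adjusted p = 0.165 with an estimated correlation), with a median log2 change of only -0.07. After median-of-ratios rescaling 10 were lower, and without control replicate 4 there were 22. The ratios of RPL11, RPL12, RPL31 and RPL5 (ENSDARG00000020197) were 0.869, 0.885, 0.908 and 0.924. Of 43 glycolysis and hypoxia genes 13 rose and 5 fell (15 and 7 over the list alone; camera adjusted p = 0.00738, adjusted p = 0.164 with an estimated correlation). Glycolytic enzyme genes led the increases, PKM (ENSDARG00000099860) 1.88-fold, GPI (ENSDARG00000103826) 1.53-fold and TPI1 (ENSDARG00000040988) 1.21-fold, whereas the oxygen sensor gene EGLN3 fell to a ratio of 0.348. The other members that fell, named after their values were seen, were TPI1 (ENSDARG00000025012, ratio 0.69), ANKRD37 (0.559), LDHB (0.938) and hif1al (0.934). Without gene IDs that share a symbol, PKM, GPI and TPI1 among them, the list's direction turned and its call was lost (camera adjusted p = 0.941). Of 15 histone genes 5 fell and 0 rose (6 over the list alone; camera adjusted p = 0.014, adjusted p = 0.164 with an estimated correlation). Among them were H2AZ2, a variant made outside S-phase, h2ax and hist2h2l, with ratios of 0.915, 0.799 and 0.878. Another, h2ax1 (ratio 0.947), was named after its value was seen. The mean of the histone list per library did not separate the groups by an exact permutation test (p = 0.143). It was 5.149 ± 0.23 in controls and 4.924 ± 0.16 in mutants on the log2 scale (SD).

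Genes of cilia and of the pathways that signal through them moved little as groups. Of 37 transition zone and nephronophthisis genes, 2 rose and 4 fell, RPGRIP1L included (the same over the list alone; camera adjusted p = 0.404). The transition zone gene tmem107 (ENSDARG00000059150) had a ratio of 0.726 and KIF7 one of 0.802, and nphp4 (1.28-fold) and CEP83 (ratio 0.744) were named after their values were seen. Of 32 intraflagellar transport and BBSome genes 3 rose (KIF3C ENSDARG00000079500 at 1.43-fold, IFT140 at 1.27-fold and BBS2 at 1.2-fold) and BBIP1 fell to a ratio of 0.805 (3 and 1 over the list alone; camera adjusted p = 0.276). Of 41 motile cilia genes 2 rose and 4 fell (1 and 2 over the list alone; camera adjusted p = 0.209), with CCDC39 1.74-fold higher and CFAP298, DNAH11 and DRC1 at ratios of 0.769, 0.591 and 0.666. LRRC23 (1.46-fold) and DNAL1 (ENSDARG00000034042, ratio 0.87), the other members past the threshold, were named after their values were seen. The call of DRC1 was lost without any 1 of 5 libraries (limma adjusted p of up to 0.0831). Among 27 Hedgehog ligands and targets 0 rose and 2 fell, nkx2.9 (ratio 0.809) and GAS1 (ENSDARG00000077298, ratio 0.905), with the same counts over the list alone and a camera adjusted p = 0.985. HHIP (ratio 1.12) and OLIG2 (ratio 1.1) did not pass, but both passed after quantile normalization (limma adjusted p = 0.0313 and 0.0425), and HHIP without control replicate 1 (0.0221). Of 21 canonical Wnt targets 0 rose and 3 fell, namely MYC (ENSDARG00000045695, ratio 0.812), sp5l (0.583) and cdx4 (0.654), with 2 lower over the list alone and a camera adjusted p = 0.711, and AXIN2 did not pass (ratio 1.06) unless rescaled (adjusted p = 0.0272 with median-of-ratios). The call of cdx4 was lost without any 1 of 6 libraries, with an adjusted p of up to 0.092. Of 30 planar cell polarity genes 0 rose and 2 fell, FZD7 (ENSDARG00000060004, ratio 0.93) and INTU (0.727), the same over the list alone (camera adjusted p = 0.714), while dact2 and FAT1 (ENSDARG00000017591) had ratios of 0.889 and 0.905 and did not pass. Leaving out control replicate 2 brought FAT1 past the threshold (limma adjusted p = 0.0462), and leaving out mutant replicate 1 took INTU off it (0.0501).

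Genes near rpgrip1l were examined because alleles linked to a selected mutation are inherited with it. Changed genes made up 28 of the 103 tested among its nearest 100 placed neighbours on each side and 2649 of 11597 (22.8%) elsewhere, a difference that did not pass Fisher's exact test (odds ratio 1.26, 95% interval 0.785 to 1.98, p = 0.29). Over the whole chromosome 94 of 368 changed (odds ratio 1.16, 95% interval 0.906 to 1.48, p = 0.231 by Fisher's exact test), over the nearest 50 on each side 14 of 67 (odds ratio 0.89, p = 0.772) and over the nearest 25 on each side 7 of 34 (odds ratio 0.874, p = 0.841). The difference passed with an adjusted p under 0.01 (odds ratio 1.74, Fisher's exact p = 0.0421), with genes of any level (1.56, p = 0.034), without control replicate 1 (1.65, p = 0.0318) and without mutant replicate 3 (1.57, p = 0.0473). With a log2 change of at least 1 required, 5 of the 103 neighbours and 31 of 11597 other genes passed (odds ratio 19, 95% interval 5.65 to 50.8, Fisher's exact p = 1.46e-05). All 5 were lower in mutants: zgc:173585, zgc:110216, si:dkey-261m9.6, dbndd1 and trpm1b, of which zgc:110216 (from 3.98 ± 0.34 to 0.652 ± 0.577 TPM) and si:dkey-261m9.6 (from 7.22 ± 1.23 to 2.53 ± 1.47 TPM; SD, n = 4 each) were named after their values were seen.

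**Figure D3:**
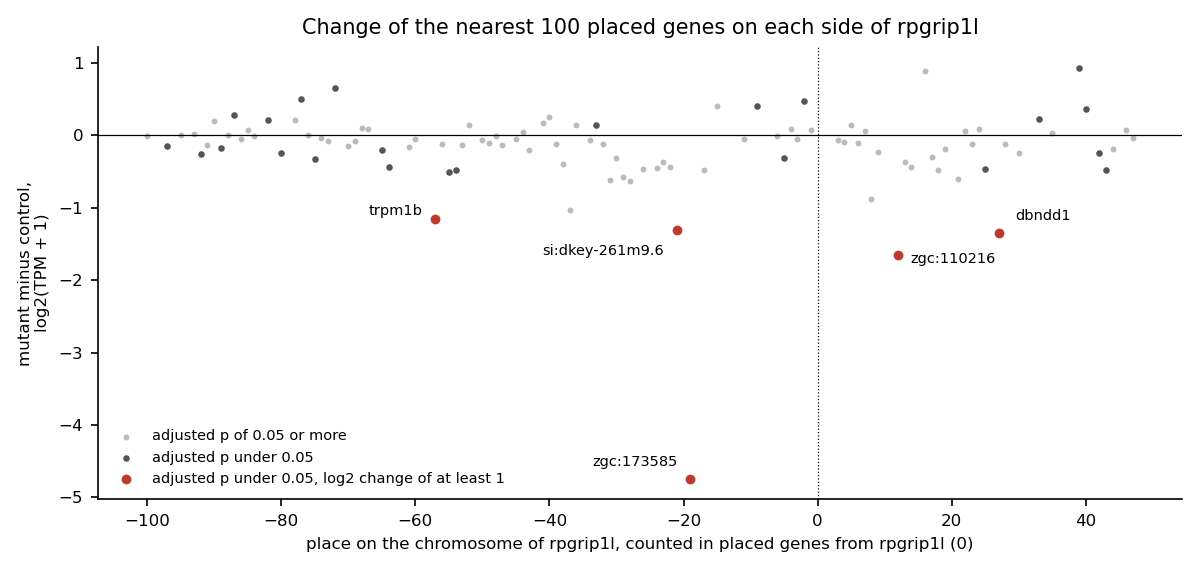
Log2 change of the tested genes among the nearest 100 placed genes on each side of rpgrip1l (vertical axis, mutant minus control on log2(TPM + 1)) against their place, counted in genes from rpgrip1l along the RefSeq GRCz12tu order; rpgrip1l lies near a chromosome end, so fewer genes lie to its right. The 5 red points, from zgc:173585 at -4.74 to trpm1b at -1.16, are all below 0.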

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

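The tests of linkage, light, scaling and developmental age in this part were chosen after the results they bear on had been seen, whereas the count of other splits of the libraries was planned. Of the 35 splits of the 8 libraries into 4 and 4, only the real one (1 split) gave as many changed genes (3745, against 3 in the highest of the others), as many genes changed by at least 1 on the log2 scale (68, against 2), as many lists past camera (18, against 16) and as many with an estimated correlation (5, against 0). The real split thus ranked first for the 4 counts, narrowly for lists at the preset correlation, which is the best rank that 35 splits allow. In the other splits the genotype difference adds to the spread within groups. Their low counts are therefore not those of unchanged data, and no chance explanation is excluded by them. A chance difference between clutches or pools stays open as well, since their number is not given. Larvae that lack the maternal function have mutant mothers, whose offspring cannot be wild type. If the controls are wild type, as labelled, mother and clutch cannot be told apart from genotype in any of the 8 libraries. The 16 splits that put 3 controls on a side keep part of the genotype difference and passed 8 to 16 lists, and the 18 even splits passed at most 1.

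Large changes cluster near the mutated gene. Of 368 genes tested on its chromosome, 5 of the 103 among the nearest 100 placed genes on each side and 1 of the other 265 changed by at least 1 on the log2 scale (Fisher's exact p = 0.00744), as alleles linked to the mutation would give. Placeholder-named genes do not account for all of it, since the odds ratio without them was 13 (95% interval 1.46 to 54.8, Fisher's exact p = 0.0125), although this rests on 2 genes, dbndd1 and trpm1b, and among the nearest 50 on each side it did not pass (11.6, 95% interval 0.274 to 75.1, p = 0.0881) and among the nearest 25 on each side 0 of 18 changed as much. Reads shared between multicopy genes were not tested, and loss of rpgrip1l acting on its neighbours cannot be told apart from linked alleles for these 5 genes, because the mutation and its chromosome came together in every mutant library, and a strain difference from the reference that prevents reads from being assigned stays open as well. The decreases of dbndd1, trpm1b and zgc:173585 may therefore reflect the haplotype and not the loss of rpgrip1l.

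Light-induced clock genes are higher in mutants. Scaling of the libraries is argued against, since after median-of-ratios rescaling 11 members of the light-induced list were still higher and the list's mean differed by 0.59 on the log2 scale (3.47 ± 0.037 in controls and 4.06 ± 0.0073 in mutants), against a median change of 0.212. The 25 core clock genes outside that list were higher by 0.172 on average on the log2 scale, with a median of 0.052 and 6 of them higher (3.032 ± 0.028 in controls and 3.204 ± 0.026 in mutants, exact permutation p = 0.0286, the smallest possible). The transition zone and motile cilia lists, which did not pass camera, reached the same permutation p. It therefore does not set these clock genes apart. Unequal light or time of day at collection cannot be told apart from genotype, because no label gives the time, lighting or batch of collection and each group could have been collected as a whole. A response of these genes to loss of nphp8 stays open and was not tested.

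Lens, erythroid and muscle genes are higher in mutants. Scaling of the libraries is argued against, as the lowest of the 3 list medians after median-of-ratios rescaling was 0.189 and their means still differed by more than the spread (the least, in muscle, by 0.19, from 6.627 ± 0.0047 to 6.818 ± 0.0098). A difference in developmental age between the groups may be involved and cannot be told apart from genotype: hatching gland genes, which decline around hatching, were lower by -0.213 on average, but exocrine pancreas and gut genes, which rise in the days after, were also lower (-0.234), and neither list passed camera with an estimated correlation (adjusted p = 0.0782 and 0.199). The condition on the estimated correlation was added after both values had been seen. Without it, the pancreas and gut list would have counted against a common difference in age and the hatching gland list for an advance of some tissues.

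Single libraries stood apart from the other 3 of their group, by more than Dixon's 95% limit on the gap over the range, in 16 of 336 gene and group combinations, and chance gives about 1 in 20, or 16.8. Control replicate 1 stood apart for SERPINH1 (ENSDARG00000019949, 344.22 TPM against 328.81 to 330.56 TPM in the others), mt-nd4l (827.36 against 786.5 to 790.11 TPM) and crybb1l1 (168.16 against 164.58 to 164.93 TPM). Control replicate 2 stood apart for FAT1 (ENSDARG00000017591, 9.67 against 10.73 to 10.85 TPM), PAICS (525.1 against 537.64 to 539.22 TPM) and TGFBI (129.38 against 133.87 to 134.61 TPM). Control replicate 3 stood apart for CRY1 (ENSDARG00000045768, 2.72 against 3.14 to 3.18 TPM), BBS2 (6.77 against 6.46 to 6.51 TPM) and MATN3 (ENSDARG00000069245, 7.78 against 7.47 to 7.5 TPM). Mutant replicate 2 stood apart for H2AZ2 (264.01 against 272.8 to 274.07 TPM) and rorcb (1.27 against 0.86 to 0.93 TPM). Mutant replicate 3 stood apart for SLC4A4 (ENSDARG00000013730, 8.2 against 7.83 to 7.86 TPM), ATF3 (6.05 against 4.92 to 5.09 TPM), gpx4a (456.45 against 437.16 to 439.88 TPM) and he1.1 (3708.2 against 3541.08 to 3567.57 TPM), and mutant replicate 4 for dbndd1 (0.4 against 0.34 to 0.35 TPM).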

How the results depend on the processing

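All alternatives were planned except the removal of shared list members, shared symbols or symbols that also name another gene and the counts of large changes in other windows or without placeholder names near rpgrip1l, which were chosen after seeing the data. The number of genes changed at an adjusted p under 0.05 lay between 2932 and 3837 under the alternatives, with 4324 at an unadjusted p under 0.05 by the exact permutation test per gene, and between 2989 and 3254 when a library was left out. The fall of rpgrip1l kept its call throughout (log2 change -1.57 at a pseudocount of 0.1, and -1.01 to -0.93 when a library was left out). The count of genes changed by at least 1 was 147 at a pseudocount of 0.1 and 17 at 5, which follows from the scale, and 36 among genes of at least 5 TPM, where fewer genes were tested. Of 3591 values of named genes under 21 settings, 3485 kept their call and 0 changed sign with a call, 76 lost it and 30 gained one. In at least 1 of the 3 rescalings, BMAL1 (ENSDARG00000035732), rorcb, HHIP, OLIG2, AXIN2 and ELOVL6 passed and DCP2, cmlc1 and EFNB2 (ENSDARG00000020164) did not. Of 819 counts of list members, 764 stayed within 1.5 times. TPM keeps no depth, so changes of genes at a few TPM cannot be weighed by their reads. Unless said, the cause of a change below was not tested.

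Of the 39 lists, 18 passed camera. The count was 17 to 20 when a library was left out and 15 among genes of at least 5 TPM. It was 16 without gene IDs that share a symbol and 17 without members whose symbol also names another gene. With an estimated correlation 5 passed, with fry for a balance of direction 30, and with fry for change in either direction 39. Neither fry test compares a list with other genes, so a call by fry does not set a list apart from them. With an estimated correlation these lists lost their call: core clock (adjusted p = 0.0621), innate immunity (0.0512), hatching gland (0.0782), liver and yolk syncytial layer (0.12), heat shock (0.124), output factors, glycolysis, mitochondrial transcripts, neurons, notochord and matrix, and histones (each 0.164), ribosomal proteins (0.165) and exocrine pancreas (0.199). With fry these gained one: myeloid (adjusted p = 0.000728), glucocorticoid (0.00107), transition zone (0.00457), motile cilia (0.00473), NRF2 (0.00547), pineal (0.00608), skin (0.00973), p53 (0.0125), Notch (0.0144), heart (0.031), left-right (0.0437) and intraflagellar transport (0.0488). Among genes of at least 5 TPM, neurons (0.0653) and exocrine pancreas (0.155) lost theirs, and the output factor, pineal and left-right lists had under 5 members left and were not tested. Nor was the pineal list without shared symbols. Without gene IDs sharing a symbol, glycolysis turned (0.941), innate immunity (0.075), neurons (0.63) and exocrine pancreas (0.35) lost their call, and Notch (0.0287) and p53 (0.0132) gained one. Without members whose symbol also names another gene, neurons (0.056) and exocrine pancreas (0.0591) lost theirs and pineal (0.0496) gained one. When a library was left out, camera's adjusted p ran from 0.0347 to 0.119 for pineal, 0.0214 to 0.0641 for exocrine pancreas, 0.0378 to 0.094 for skin, 0.0362 to 0.138 for p53, 0.0437 to 0.141 for Notch and 0.0129 to 0.0758 for neurons.

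The odds ratio near rpgrip1l passed Fisher's exact test at an adjusted p under 0.01 (1.74) and without a filter (1.56), and ran from 1.31 to 1.65 when a library was left out. For changes of at least 1 it was 19, or 34 and 23 for the nearest 25 and 50 on each side, 6.24 for the whole chromosome and 13 without placeholder names. The whole-chromosome value is not particular to this chromosome, as another had 9 such genes of 432 tested against 6 of 368.

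Libraries of the 2 groups share replicate numbers, but deviations of same-numbered libraries from their group means did not go together (correlations -0.029, -0.062, -0.1 and -0.051), and 0 of 8 libraries correlated best with its own number. With the replicate block 2932 genes changed and 17 lists passed; the exocrine pancreas list lost its call (adjusted p = 0.067), and 4 named genes lost theirs (CRX, DRC1, DCP2 and cmlc1). No other call changed with the block among the lists, the genes named by the rule, rpgrip1l and its nearest 100 neighbours on each side at an adjusted p under 0.05; other named genes and large changes near rpgrip1l were not compared.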

Other observations

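In this part the tests without gene IDs that share a symbol or without members whose symbol also names another gene were chosen after the results were seen, the others were planned, and members named outside the rule are said to be so. Other gene groups did not pass camera with the preset correlation, and most moved in mixed directions. In the p53 list, however, nearly all changed genes fell. Of 45 skin and ionocyte genes 9 rose and 19 fell (10 and 21 over the list alone; camera adjusted p = 0.0651). The actinodin genes and1, and2 and and3, which build the fin fold, rose 1.48-fold, 1.65-fold and 1.6-fold, from 46.4 ± 0.515 to 76.3 ± 2.37 TPM for and2 (SD, n = 4 each), and the keratin gene krt17 fell from 102.4 ± 4.41 to 65.3 ± 1.61 TPM. The skin list passed without control replicate 2 (camera adjusted p = 0.0378) and without mutant replicate 3 (0.0429). Among 26 members of the Notch list 7 rose and 3 fell (7 and 4 over the list alone; camera adjusted p = 0.0651), with her12, her15.1, her15.2 and her4.4 at 1.22-fold, 1.46-fold, 1.19-fold and 1.17-fold. Several of these are near-identical tandem copies, and the 3 that fell, named after their values were seen, were her8a (ratio 0.85), HEY2 (0.821) and dlc (0.894). Neither DES, the muscle gene desmin, which entered this list through a synonym of notch1a, nor DLD, whose symbol also names a dehydrogenase gene, passed, and without them the list had a camera adjusted p = 0.063. The list of 26 passed without mutant replicate 1 (camera adjusted p = 0.0437) and without gene IDs that share a symbol, DES among them (0.0287). Of 24 myeloid genes 4 rose and 6 fell (the same over the list alone; camera adjusted p = 0.209), with the cathepsin gene ctss2.1 falling from 176.7 ± 3.48 to 115.9 ± 0.442 TPM, the MFAP4 copies ENSDARG00000090783 and ENSDARG00000090557 at ratios of 0.579 and 0.673, and the neutrophil gene lyz at 1.1-fold. The other 3 that rose, named after their values were seen, were LECT2 (ENSDARG00000033227, 1.28-fold), apoeb (1.05-fold) and nccrp1 (1.09-fold). Of 31 p53 and apoptosis genes 1 rose and 9 fell (2 and 11 over the list alone; camera adjusted p = 0.0669), including BTG2 (ratio 0.782), TP53INP1 (0.806), rps27l (0.692) and SESN1 (0.88), while the riser, named after its value was seen, was PLK2 (ENSDARG00000090752, 1.25-fold). The p53 list passed without control replicate 3 (camera adjusted p = 0.0362) and without gene IDs that share a symbol (0.0132).

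Kidney, hormone and metabolic lists were split as well. Of 39 pronephros genes 2 rose and 4 fell (1 and 4 over the list alone; camera adjusted p = 0.946), the latter being the transport genes TRPV6 (ratio 0.666), SLC4A4 (ENSDARG00000013730, 0.808), TRPM7 (0.859) and KCNJ1 (ENSDARG00000089060, 0.743). Both SLC20A1 copies (ENSDARG00000010641 at 1.09-fold and ENSDARG00000020114 at 1.39-fold), named after their values were seen, rose. Of 31 glucocorticoid and metabolic hormone targets 5 rose and 10 fell (the same over the list alone; camera adjusted p = 0.317), with DDIT4, G6PC1 (ENSDARG00000013721) and CYP17A1 at ratios of 0.682, 0.757 and 0.75 and pck2 at 1.2-fold. STAR (1.47-fold), mmp13a (2.0-fold), PDK2 (ENSDARG00000020876, 1.18-fold) and g6pc1a.1 (1.86-fold) also rose and were named after their values were seen. Of 27 NRF2 and oxidative stress genes 5 rose and 8 fell (7 and 9 over the list alone; camera adjusted p = 0.404), with prdx1 (ENSDARG00000058734) 1.3-fold higher and gsta.2, NQO1 and gpx4a at ratios of 0.746, 0.783 and 0.788. The other 4 that rose, named after their values were seen, were SOD1 (1.25-fold), TXNRD3 (1.17-fold), nfe2l2b (1.39-fold) and PRDX1 (ENSDARG00000025350, 1.04-fold). Of 27 nonsense-mediated decay genes 3 rose and 1 fell (2 and 0 over the list alone; camera adjusted p = 0.227), with the exon junction factor RNPS1 rising from 6.70 ± 0.203 to 12.1 ± 1.04 TPM (SD, n = 4 each), XRN2 1.13-fold and upf3a 1.3-fold higher, and DCP2 at a ratio of 0.92. The calls of upf3a and DCP2 were lost without any 1 of 6 and of 7 libraries (limma adjusted p of up to 0.0962 and 0.11). Of 26 sterol synthesis genes 4 rose and 1 fell (the same over the list alone; camera adjusted p = 0.327; median -0.016 and mean 0.04 differ in sign, and the test points upwards), with MSMO1 and HMGCS1 1.39-fold and 1.22-fold higher and IDI1 at a ratio of 0.866; SQLE (ENSDARG00000079946, 1.27-fold), which also rose, was named after its value was seen. Of 46 S-phase and mitosis genes 4 rose and 7 fell (the same over the list alone; camera adjusted p = 0.598), with GMNN, CDC20 and PRC1 (ENSDARG00000005993) at ratios of 0.849, 0.862 and 0.888 and RRM1 at 1.1-fold. The replication genes MCM2 (1.09-fold), MCM5 (1.06-fold) and MCM7 (1.08-fold), named after their values were seen, rose as well. The medians of the glucocorticoid, sterol and S-phase lists changed sign when libraries were rescaled without mitochondrial and the 50 most abundant genes, and that of the S-phase list also with quantile normalization.

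The remaining tissue lists did not pass camera with the preset correlation either. Of 11 pineal and phototransduction genes 4 rose and 1 fell (the same over the list alone; camera adjusted p = 0.0651), with ARR3 (ENSDARG00000056511), CRX (ENSDARG00000043483) and GNGT2 (ENSDARG00000103543) rising 1.93-fold, 1.54-fold and 1.92-fold at levels under 2 TPM and rbp4l at a ratio of 0.875. The other riser, crx (ENSDARG00000011989, 1.55-fold), was named after its value was seen. This list passed without control replicate 1 (camera adjusted p = 0.0347), mutant replicate 1 (0.0371) or mutant replicate 3 (0.0451) and without members whose symbol also names another gene (0.0496), whereas the calls of CRX (ENSDARG00000043483) and GNGT2 were lost without any 1 of 7 and of 6 libraries (limma adjusted p of up to 0.0854 and 0.0906). Of 32 pigment cell genes 10 rose and 4 fell (the same over the list alone; camera adjusted p = 0.229; median 0.022 and mean -0.011 differ in sign, and the test points upwards), with TYRP1 (ENSDARG00000056151) and pmela 1.2-fold and 1.18-fold higher and trpm1b and PAICS at ratios of 0.414 and 0.839. TRPM1 (ratio 0.53) and gch2 (0.939), named after their values were seen, were the other members that fell. Of 18 heart genes 3 rose and 1 fell (the same over the list alone; camera adjusted p = 0.294), with the natriuretic peptide genes nppb and nppa 1.66-fold and 1.22-fold, actc1a 1.08-fold and cmlc1 at a ratio of 0.909, a call lost without any 1 of 5 libraries (limma adjusted p of up to 0.0859). Of 33 vascular genes 1 rose and 3 fell (1 and 2 over the list alone; camera adjusted p = 0.313), namely plvapb (1.35-fold), klf2b (ratio 0.78), aplnra (0.843) and EFNB2 (ENSDARG00000020164, 0.872). The last 3 calls were lost without any 1 of 4, 2 and 6 libraries (limma adjusted p of up to 0.0596, 0.0544 and 0.105). Of 5 members of the left-right list BMP4 alone rose (1.14-fold; 3 over the list alone; camera adjusted p = 0.143), and the fatty acid elongase gene ELOVL6 (ratio 1.19) and lft1 (1.36) did not pass, though ELOVL6 did without control replicate 4 (limma adjusted p = 0.00828).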
